A study of Homo sapiens with 13 samples.

How the data were processed

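Bulk RNA-seq and ATAC-seq were collected from human alveolar type 2 (AT2) cells, the surfactant-producing epithelial cells of the alveolus, from lungs with idiopathic pulmonary fibrosis (IPF) and from normal lungs. ATAC-seq, which marks open chromatin by transposase insertion, was also collected from basal cells of the proximal airways of normal lungs. Per the labels' protocols, distal parenchyma was dissected and digested with elastase. Cells were enriched on a Percoll gradient, depleted of immune cells by IgG panning, and selected with beads against EpCAM, a surface protein of all lung epithelium. RNA libraries were polyA selected per the extract protocol, while the molecule label reads polyA RNA for 1 RNA library and total RNA for the other 4.

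The RNA-seq data were a table of raw counts per gene, deposited by the authors with no normalization. It held 30997 Entrez gene identifiers, of which 30905 were paired with a symbol and 92 were not. The submitters' processing notes name FastQC, STAR, DESeq2, BWA, Genrich, HOMER and the build hg38, without versions or roles. The read counter, its annotation and its strand setting are not given in the sources used here. Reads of genes with near-identical copies (the surfactant protein A genes, the keratin 6, 14, 16 and 17 genes, the alpha globin genes, FAM230 and RNU1 copies) are therefore uncertain, as are those of overlapping and antisense genes.

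The ATAC-seq data were 1 peak list per library, called per library, per the files themselves. The deposited AT2 lists gave each peak a score capped at 1000, a signal value, and the −log10 of its p and q values, all as the authors' peak caller wrote them. The deposited basal lists gave a score only. These are the authors' values, and they were used only to rank or filter peaks within a list. Depth behind the peaks, duplicate removal and calling thresholds are not given in the sources used here, and no read coverage was analysed here.

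Groups followed the sample titles. RNA-seq compared 2 IPF with 3 normal libraries, and ATAC-seq compared 3 IPF with 3 normal AT2 libraries and these 6 with 2 basal libraries. Within an assay the titles give each library its own donor. The p-values of single genes and of permutations over libraries therefore measure the spread between donors.

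RNA counts were tested with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood F test with TMM scaling and filterByExpr (minimum count 10). Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Before testing, 253 genes whose level follows a donor's sex or common genotype, immune receptor segments included, were removed. CPM values are TMM scaled, and log2 CPM used a prior count of 2. Totals were 16239811 and 30998824 counts in IPF replicates 1 and 2 and 28861198, 30472047 and 32500869 in normal replicates 1, 2 and 3. Counts were simulated for this comparison over 17661 genes, all with a biological coefficient of variation of 0.38. Of these, 200 genes, drawn from those with higher counts, were changed. The test recovered 8.8% of genes changed 2-fold, 56.1% of those changed 4-fold and 100% of those changed 16-fold, and 4.4% of its calls were false. Fewer genes were changed than were called in the data, and variation was equal across genes, so these rates need not hold for the data.

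In all, 32 gene lists with 580 genes were written before the data were examined, as were the design, the rule for named genes and most of the alternative settings. Of the genes, 515 were tested. Lists with at least 5 tested members (29 lists) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, with adjustment over these lists. Camera with an estimated correlation and fry were run beside it. Camera sets the genes of a list against the other genes of the same libraries. Its p-values at the preset correlation therefore measure mostly the spread across genes, not that between donors. Estimated correlations ran from −0.04 for senescence to 0.877 for ciliated genes, with 0.046 for AT2 identity, 0.432 for lipid synthesis and 0.335 for basal genes. No list passed camera with an estimated correlation. The lists covered AT2 identity, lipid synthesis, AT1, transitional and basaloid, basal, airway secretory, ciliated, macrophage, lymphocyte, granulocyte, mesenchymal, endothelial and erythroid genes. They also covered TGF-beta, p53, cell cycle, TRIP13 partners, stress, interferon, inflammatory, MHC class II, NRF2, hypoxia, oxidative phosphorylation, senescence, telomere, Wnt, EMT, chromatin, dissociation, mitochondrially encoded and histone genes.

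The named genes were TRIP13, which the series title names, and the 12 highest and 12 lowest log2 fold changes among called protein-coding genes. These needed a mean of at least 5 CPM and IPF libraries outside the range of the normal ones. From each list, up to 4 members with the smallest adjusted p were added, and 2 with the highest mean CPM where no member was called. The text names 97 genes for their expression, and other genes and regions that these rules select are not reported here. Regions were named by the mean rank of the authors' score and signal.

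Peaks were analysed on autosomes in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1. An overlap needed at least 1 bp. Libraries were compared by peak number, by the Jaccard index in base pairs and by regions merged over libraries, with exact permutation tests over libraries. Shares carry Wilson 95% intervals, which cover counting error only. Coordinates are on hg38 as deposited. No genome sequence was used here. The gene table (GRCh38.p14) gave gene starts and ends without strand, so the planned distance to a transcription start was replaced by a peak within 1 kb of either end of the gene. Gene bodies were extended by 5 kb on both sides. The overlap counting recovered all 1872 regions of a simulated set.

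Alternatives covered other tests (DESeq2 1.42.0, limma-voom), scalings, count filters, a 2-fold test, the replicate number as a block, stricter or equal-sized peak sets, a 50% overlap, a 5 kb window, removal of peaks with a signal over 10 times the library median, and each library left out in turn. Counts thinned to the total of IPF replicate 1, more scalings for the lists, libraries left out of the peak share of the AT2 list, and the block for peak numbers were added after seeing the data. No file column of another sample was present or used.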

Results

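RNA-seq of AT2 cells covered 2 IPF and 3 normal libraries with 16239811 to 32500869 counts each. ATAC-seq covered 3 IPF AT2, 3 normal AT2 and 2 normal basal libraries. Surfactant protein genes led the normal AT2 libraries. SFTPC was the top gene of normal replicates 1 and 2 with 4.72% and 7.47% of counts, and SFTPB that of normal replicate 3 with 4.39%. The 10 most abundant genes together took 20.27% to 28.27% of counts in normal and 8.64% to 9.15% in IPF libraries. Between 21117 and 22496 genes were detected per library. The first principal component held 60.8% of the variance and separated both IPF libraries from the normal ones. Correlations of log2 CPM across genes, which are not independent replicates, were 0.937 within IPF, 0.953 to 0.964 within normal and 0.859 to 0.919 between groups. No pair of libraries agreed within sampling noise.

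The first comparison asked which genes differed in expression between IPF and normal AT2 cells. In IPF, 17 of 23 AT2 identity and surfactant genes and 14 of 22 lipid synthesis genes were lower and 15 of 18 basal genes higher, in lists that did not pass camera with an estimated correlation (adjusted p = 0.159, 0.38 and 0.358). CLDN18, an alveolar tight junction gene, was at 49.5 ± 26.2 CPM in IPF (SD, n = 2) and 920 ± 244 CPM in normal cells (SD, n = 3). COL17A1, which anchors basal cells to the basement membrane, was at 66.7 ± 6.46 against 2.18 ± 0.315 CPM, and KRT5, the classical basal keratin, at 838 ± 340 against 37.9 ± 13.8 CPM. Of 17949 genes tested with edgeR, 713 were higher and 771 lower in IPF. At least 4-fold changes accounted for 512 of the higher and 389 of the lower genes. Protein-coding genes made up 621 and 688 of the calls, and long noncoding RNAs 78 and 77.

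All 1484 called genes had non-overlapping groups, as did 49.7% of all tested genes, where chance gives 20%. The fits without IPF replicate 1 and without IPF replicate 2 each left 1 IPF library. The number of called genes depended on single libraries. It was 0 with edgeR without IPF replicate 1 (4093 genes at an unadjusted p under 0.05), which left 1 IPF library whose spread was assumed to be that of the normal group. It was 963 without IPF replicate 2 and 605, 703 and 569 without normal replicates 1, 2 and 3. DESeq2 called 3429 genes and limma-voom 1563. Higher genes were 48% of the calls with TMM, 57% with upper-quartile scaling, which moved the median log2 fold change of all genes to 0.15, and 78% with library size only, which moved it to 0.40.

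TRIP13, an ATPase of the spindle checkpoint and the gene of the series title, was at 28.9 and 65.0 CPM in the IPF libraries and at 12.8, 18.1 and 5.02 CPM in the normal ones. The means were 46.9 ± 25.5 (SD, n = 2) and 12 ± 6.59 CPM (SD, n = 3). Its log2 fold change of 1.97 (SE 0.553, 95% interval 0.67 to 3.27) did not pass with edgeR, adjusted p = 0.0711. It passed with DESeq2 (adjusted p = 0.00714) and with library size only in edgeR (adjusted p = 0.0426). It also passed with the replicate number as a block (log2 fold change 1.51, adjusted p = 0.0486). That block pairs libraries of different people. Normal replicate 3, at 5.02 CPM the lowest for TRIP13, has no IPF library of its number and so drops out of the contrast. Over all alternatives the adjusted p lay between 0.00714 and 0.288. The log2 fold change was 1.21 without IPF replicate 2 and at most 2.43, without IPF replicate 1. TRIP13 (Entrez 9319) lies on chromosome 5 from 892884 to 919348.

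**Figure D1:**
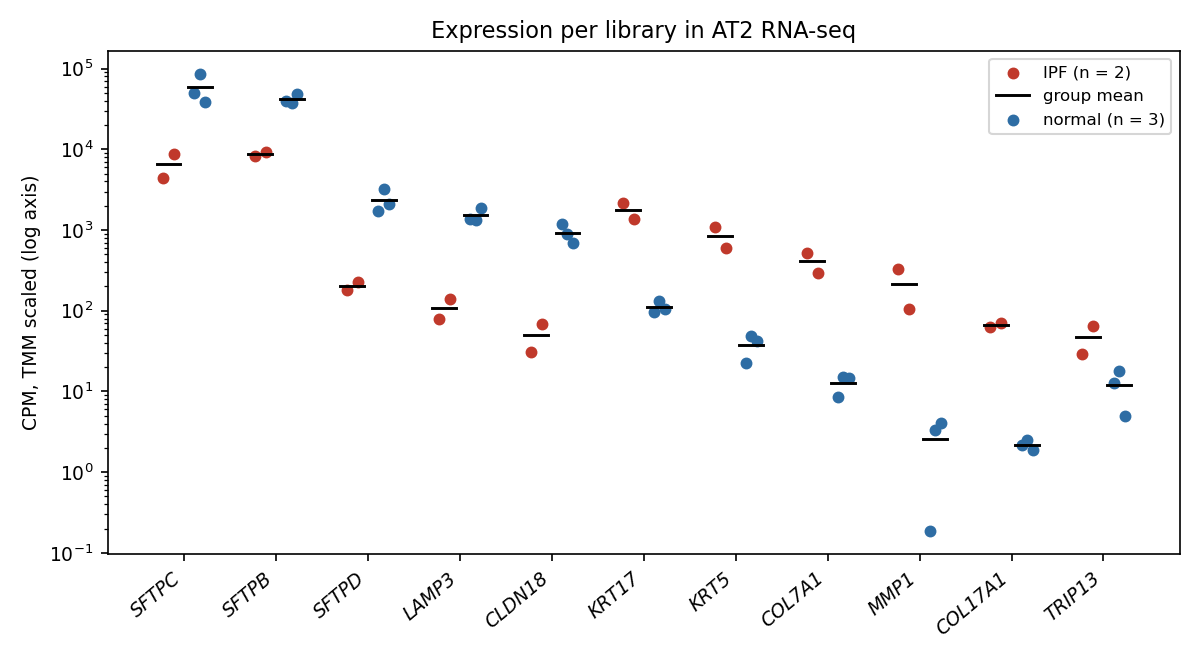
Expression of 11 genes in each AT2 RNA-seq library, as TMM-scaled CPM on a log axis. Points are libraries (2 IPF, 3 normal) and bars are group means. The surfactant genes, LAMP3 and CLDN18 lie lower in both IPF libraries, for example 6557 against 58475 CPM for the means of SFTPC, while the keratins, collagens and MMP1 lie higher.

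Values in parentheses after a gene are log2 fold changes, IPF minus normal. Among called protein-coding genes with a mean of at least 5 CPM, the highest log2 fold change was that of MMP1, an interstitial collagenase, at 6.40 (SE 1.06, edgeR adjusted p = 0.0194), with 216 ± 155 CPM in IPF (SD, n = 2) and 2.54 ± 2.07 CPM in normal cells (SD, n = 3). The chemokine gene CXCL14 followed at 5.59. Adhesion genes among the 12 highest were DSC3 of desmosomes at 5.21, COL7A1 of anchoring fibrils at 5.00 and COL17A1 of hemidesmosomes at 4.93. SERPINB5 (4.99), S100A2 (4.96), KRT14 (4.84) and KRT6A (4.50) are expressed in basal and squamous epithelium. MDFI, an inhibitor of myogenic transcription factors, rose by 4.74 on the log2 scale, the potassium channel gene KCNN4 by 4.53 and the growth factor gene BMP7 by 4.51. Values of the keratins are uncertain because of their near-identical copies.

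The lowest fold changes were those of NOTUM, a secreted Wnt inhibitor, at −5.09 (SE 1.23, edgeR adjusted p = 0.0497) and EDNRB, an endothelin receptor, at −5.00 (SE 0.536, adjusted p = 0.0112). EDNRB was at 2.54 ± 0.399 CPM in IPF (SD, n = 2) and 82.0 ± 43.0 CPM in normal cells (SD, n = 3). The apolipoprotein gene APOH was at −4.65 and the angiotensin receptor gene AGTR2 at −4.53. GPM6A (−4.56), PRTG (−4.49), ADCY8 (−4.44), STC1 (−4.16) and TAFA5 (−4.10) had normal means of 8.29 to 33 CPM. ZNF385B was at 9.71 ± 6.03 against 199 ± 9.53 CPM, a log2 fold change of −4.35. CLDN18 was at −4.21.

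Most tested genes that define AT2 cells were lower in IPF. Of 23 tested AT2 identity and surfactant genes, 17 were lower and 0 higher over all genes, and 19 were lower adjusted over the list alone. LAMP3, a lamellar body protein, was at 109 ± 44.4 CPM in IPF (SD, n = 2) and 1514 ± 295 CPM in normal cells (SD, n = 3), a log2 fold change of −3.79 (edgeR adjusted p = 0.0129). HHIP, a hedgehog inhibitor, was at −4.08 and surfactant protein gene SFTPD at −3.54. SFTPC (−3.16, adjusted p = 0.0367) and SFTPB (−2.24, adjusted p = 0.0408) were singled out after their values were seen. The median of the list was −2.24 (SD 1.09 across genes, camera adjusted p = 8.86e-14). With an estimated correlation the list did not pass, adjusted p = 0.159. Basal and macrophage markers were higher in the same IPF libraries.

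Most tested genes of lipid and cholesterol synthesis, which supplies surfactant, were also lower. Of 22 tested genes, 14 were lower and 0 higher, and 19 were lower adjusted over the list alone. The fatty acid desaturase gene FADS1 was at 16.9 ± 3.92 CPM in IPF (SD, n = 2) and 144 ± 56.7 CPM in normal cells (SD, n = 3), a log2 fold change of −3.09. The sterol synthesis genes CYP51A1 (−2.33), DHCR7 (−2.25) and SC5D (−2.08) fell as well. The median was −1.86 (SD 0.796, camera adjusted p = 7.81e-11), and the adjusted p was 0.38 with an estimated correlation.

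Basal cell genes had the highest median of the tested lists. Of 18 tested members, 15 were higher and 0 lower, and 15 were higher adjusted over the list alone. DSC3, SERPINB5, KRT17 (1787 ± 568 CPM in IPF, SD, n = 2; 111 ± 18.6 CPM in normal cells, SD, n = 3) and DSG3 (log2 fold change 5.93) had the smallest adjusted p-values. KRT5 (4.47) and KRT15 (3.8), named after their values were seen, were at 838 ± 340 and 604 ± 346 CPM in IPF. The median was 3.91 (SD 1.80, camera adjusted p = 4.48e-11), and the adjusted p was 0.358 with an estimated correlation. Without IPF replicate 1 the median was 2.98.

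Markers of transitional and aberrant basaloid cells, epithelial states that express keratin 17 with senescence genes, rose in part. Of 27 tested genes 9 were higher and 1 lower, and 14 were higher and 1 lower adjusted over the list alone. The cell cycle inhibitor gene CDKN2A was at 21.0 ± 3.43 CPM in IPF (SD, n = 2) and 2.17 ± 0.695 CPM in normal cells (SD, n = 3). The urokinase gene PLAU (log2 fold change 4.09) and the transcription factor gene SOX9 (2.86) rose too. The exception was the integrin gene ITGB6 at −2.21 (edgeR adjusted p = 0.0360). The median of the list was 1.30 (camera adjusted p = 2.75e-06), with an adjusted p of 0.159 with an estimated correlation. Only KRT17 and LAMB3 were shared with the basal list, 2 genes of 27.

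Some airway secretory genes were higher. Of 18 airway secretory genes, 5 were higher and 1 lower, and 9 were higher and 1 lower adjusted over the list alone. BPIFA1, a secreted airway defence protein, was at 170 ± 61.4 CPM in IPF (SD, n = 2) and 11 ± 5.98 CPM in normal cells (SD, n = 3). LCN2 (log2 fold change 2.37) and TSPAN8 (2.13) rose and CREB3L1 was lower (−1.87). The median was 1.47 (camera adjusted p = 0.00128, adjusted p = 0.596 with an estimated correlation and 0.147 with fry), and 2.30 without normal replicate 1. All 19 ciliated cell genes had positive fold changes with a median of 1.48 (SD 0.329), but 0 passed with edgeR over all genes or adjusted over the list alone (11 at an unadjusted p under 0.05, 9 called by DESeq2 and 0 by limma-voom). SNTN was at 1.88 (adjusted p = 0.0958), with DYNLRB2 at 1.63, ROPN1L at 1.78 and RSPH1 at 1.84. CAPS, at 2083 ± 349 CPM in IPF (SD, n = 2) and 651 ± 426 CPM in normal cells (SD, n = 3), and TPPP3, at 1269 ± 212 and 455 ± 256 CPM, were the most abundant. The ciliated list passed camera with adjusted p = 1.94e-04, not with an estimated correlation (adjusted p = 0.657) or fry (adjusted p = 0.315), and not without IPF replicate 2, where the median was 0.93 and the adjusted p was 0.0578.

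AT1 genes, of the flat gas-exchange cells to which AT2 cells give rise, did not pass as a group. Of 16 tested genes 1 was higher and 3 lower, and 1 was higher and 5 lower adjusted over the list alone. The aquaporin gene AQP5 rose (2.69), while RTKN2 (−2.81), the basement membrane collagen gene COL4A3 (−2.07) and the caveolin gene CAV1 (−1.46) fell. The median was −0.44 (camera adjusted p = 0.0637). It passed without IPF replicate 1 (median −0.91, adjusted p = 0.0309) and without normal replicate 2 (median −0.70, adjusted p = 0.0119).

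Markers of cells outside the epithelium were measured as background. Of 18 macrophage genes, 10 were higher and 0 lower, and 16 were higher and 1 lower adjusted over the list alone. MARCO was at 53.8 ± 18 CPM in IPF (SD, n = 2) and 8.79 ± 3.02 CPM in normal cells (SD, n = 3). TREM2 (log2 fold change 3.54), SPP1 (2.84) and TYROBP (2.26) were at 3.75, 15.9 and 12.2 CPM in IPF. The macrophage median was 2.29 (camera adjusted p = 9.48e-07, and adjusted p = 0.38 with an estimated correlation). Without IPF replicate 2 the median was 1.4. Of 11 mesenchymal genes, 3 were higher and 0 lower, and 7 were higher adjusted over the list alone. These 3 were FBLN1 (3.91), POSTN (2.57) and PDGFRA (3.45), and the median was 1.61 (camera adjusted p = 1.69e-05, and adjusted p = 0.249 with an estimated correlation). Of 12 endothelial genes, 0 were higher and 2 lower, ESAM (−3.32) and EGFL7 (−2.64), with the same number adjusted over the list alone and a median of −0.29 (camera adjusted p = 0.799). Granulocyte and mast cell genes held 1 lower gene of 8, CSF3R (−3.24), and 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.652). Of 11 lymphocyte genes 0 passed with edgeR, over all genes or adjusted over the list alone (0 at an unadjusted p under 0.05 and 0 with DESeq2 or limma-voom), with a median of 1.00 (camera adjusted p = 0.108). That list passed without IPF replicate 2 (median 1.27, adjusted p = 0.0337), while the median fell to 0.05 without IPF replicate 1, 0.354 without normal replicate 2 and 0.547 without normal replicate 1. The 4 tested erythroid genes had no call with edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05.

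**Figure D2:**
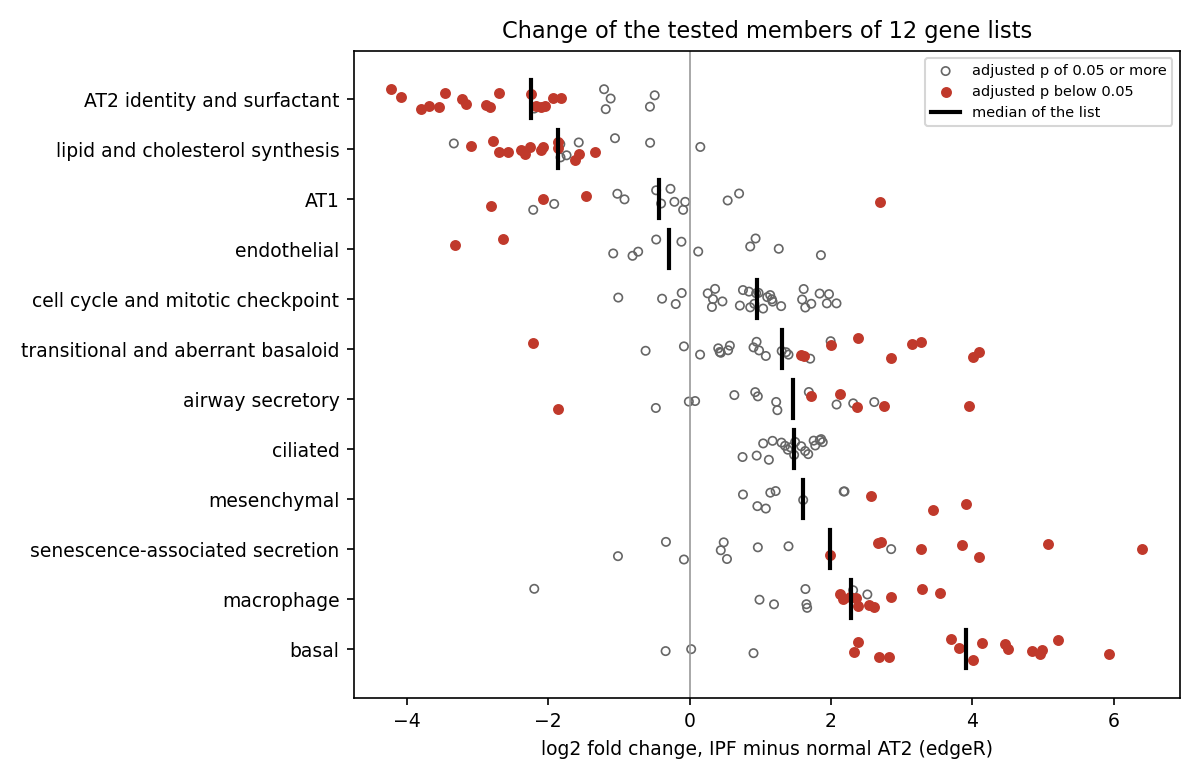
Log2 fold change between IPF and normal AT2 cells of every tested member of 12 gene lists. Each point is a gene, filled where the edgeR adjusted p was below 0.05, and the bar is the median of the list. Medians run from −2.24 for AT2 identity to 3.91 for basal genes.

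Some genes of senescence-associated secretion rose. Of 17 tested, 8 were higher and 0 lower, and 10 were higher and 1 lower adjusted over the list alone. They included IGFBP3, which binds insulin-like growth factors, at 137 ± 70.6 CPM in IPF (SD, n = 2) and 21.1 ± 6.04 CPM in normal cells (SD, n = 3), besides CDKN2A and PLAU. The list shares 5 genes with the basaloid list. Its median was 1.98 (camera adjusted p = 1.94e-04, and adjusted p = 0.214 with an estimated correlation). Of 18 genes of the p53 response, 3 were higher and 0 lower, and 9 were higher adjusted over the list alone. These were PHLDA3 (1.56), ZMAT3 (2.18) and DDB2 (1.14), while PLK3 was at 1.37 (edgeR adjusted p = 0.0543). The p53 median was 0.65 (camera adjusted p = 0.0433, adjusted p = 0.38 with an estimated correlation and 0.0564 with fry). The median was 0.42 without IPF replicate 1, and the list did not pass without IPF replicate 2 (adjusted p = 0.0616), normal replicate 1 (adjusted p = 0.0781) or normal replicate 2 (adjusted p = 0.172). Of 20 TGF-beta response genes, 5 were higher and 1 lower, and 6 were higher and 1 lower adjusted over the list alone. COL7A1, LTBP2 (2.50) and TNC (1.62) were among the higher genes and ITGB6 was the lower one. The TGF-beta median was 0.48 (camera adjusted p = 0.0637), and the list passed without IPF replicate 1 (median 0.57, adjusted p = 0.0077), while the median was 0.312 without IPF replicate 2.

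The cell cycle list, to which TRIP13 belongs, held 0 called genes. Of 30 tested genes, 26 had positive fold changes and 0 passed with edgeR, over all genes or adjusted over the list alone (12 at an unadjusted p under 0.05, 8 called by DESeq2 and 0 by limma-voom). The mitotic kinase gene PLK1 was at 1.72 (adjusted p = 0.0519), CENPF of the kinetochore at 1.59 (adjusted p = 0.0647) and the thymidylate synthase gene TYMS at 1.17 (adjusted p = 0.0802). The median was 0.96 (SD 0.749, camera adjusted p = 2.36e-04, adjusted p = 0.596 with an estimated correlation and 0.17 with fry), and 0.61 without IPF replicate 1. Of 18 HORMA-domain and DNA repair partners of TRIP13, 0 passed with edgeR, over all genes or adjusted over the list alone (6 at an unadjusted p under 0.05, 2 called by DESeq2 and 1 by limma-voom). HORMAD1, a meiotic HORMA-domain gene, was at 0.811 ± 0.601 CPM in IPF (SD, n = 2) and 0.148 ± 0.0704 CPM in normal cells (SD, n = 3). NHEJ1 of DNA end joining was at −1.33 (edgeR adjusted p = 0.0512), with XRCC6 at −0.87 and RIF1 at −0.78. The median was −0.35 (camera adjusted p = 0.652).

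The second comparison asked how open chromatin differed between IPF and normal AT2 cells. The peak lists varied more within groups than between them. IPF replicates held 1607, 946 and 12892 autosomal peaks and normal replicates 10975, 616 and 564. These peaks covered 0.568, 0.363 and 4.59 Mb in IPF and 3.77, 0.246 and 0.295 Mb in normal libraries. The log10 number of peaks was 3.43 ± 0.6 in IPF (SD, n = 3) and 3.19 ± 0.733 in normal libraries (SD, n = 3), a difference of 0.24 (two-sided exact permutation p = 0.5, where 0.1 is the smallest p possible). Without IPF replicate 3 the difference was −0.10. Peaks within 1 kb of the end of a protein-coding gene made up 55.6%, 39.5% and 67.8% of IPF lists and 55.5%, 29.1% and 2.3% of normal lists. Of 18978 autosomal protein-coding genes, 9088 had such a peak in IPF replicate 3, 6265 in normal replicate 1 and 13 in normal replicate 3.

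**Figure D3:**
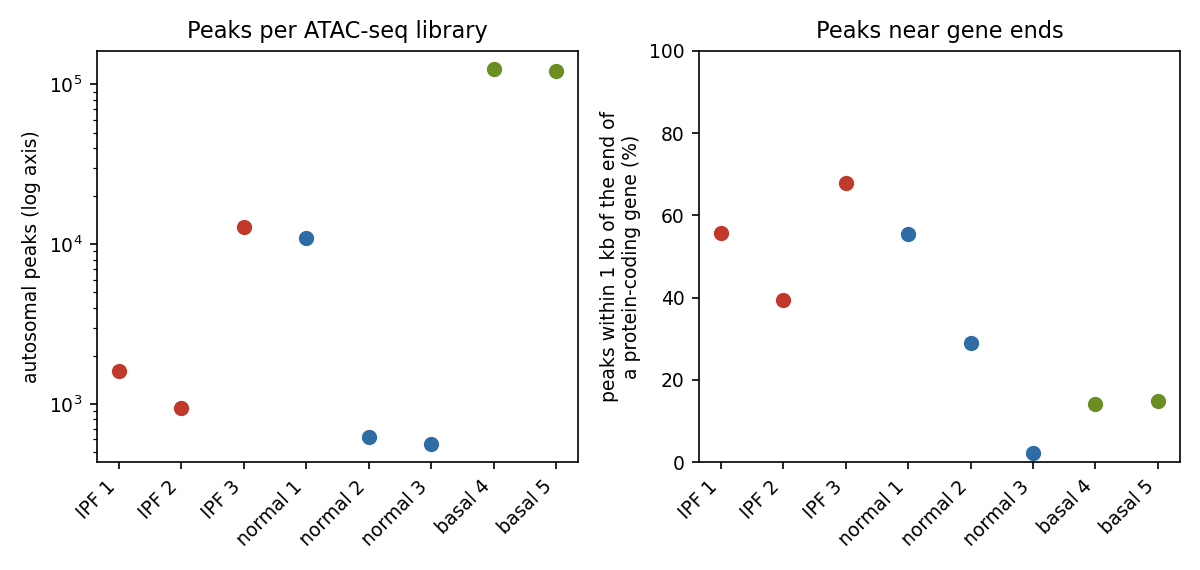
Left, autosomal peaks per ATAC-seq library on a log axis. Right, the percent of these peaks within 1 kb of the end of a protein-coding gene. Points are single libraries of IPF AT2, normal AT2 and normal basal cells. The AT2 lists range from 564 to 12892 peaks and the basal lists hold 121467 and 124117.

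No higher overlap within groups was found, though the length of the lists limits the index and each group held 1 of the pair of long lists. The Jaccard index in base pairs averaged 0.230 within groups and 0.293 between them, a difference of −0.0630 (one-sided exact permutation p = 0.6 over 10 splits). It was −0.0235 without normal replicate 1 (exact p = 0.5), −0.0402 without IPF replicate 2 and −0.0394 without extreme signal (exact p = 0.6 each). Of 16552 merged regions, 9413 were found in 1 library, 7088 in both groups and 254 in all 6 libraries. In at least 2 IPF and 0 normal libraries there were 38 regions, and 13 in at least 2 normal and 0 IPF libraries. Without normal replicate 1 the IPF number was 994, and it was 20 without IPF replicate 1, 12 without IPF replicate 3 and 58 without normal replicate 3. The normal number was 83 without IPF replicate 3, 23 without IPF replicate 2, and 2, 7 and 6 without normal replicates 1, 2 and 3.

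The regions that ranked highest by the authors' score in all 6 AT2 libraries lay on chromosome 1 from 631697 to 634967 and from 629043 to 631579, over nuclear copies of mitochondrial genes such as MTCO1P12, and on chromosome 16 from 46398184 to 46401692, outside annotated genes. Of the regions found in IPF libraries and 0 normal ones, the highest lay on chromosome 21 from 10272316 to 10272896, outside annotated genes and 248687 bp from TPTE, and on chromosome 22 from 18896225 to 18896622 in FAM230F, each in 3 of 3 IPF libraries. A region on chromosome 1 from 16666839 to 16667374 over the small nuclear RNA gene RNU1-3 was found in 2. Normal counterparts, each in 2 of 3 normal libraries, lay on chromosome 9 from 39874010 to 39874688 over FGF7P3 and on chromosome 20 from 27049828 to 27050027, outside annotated genes. Exons and introns were not told apart.

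At TRIP13 a peak was called at the lower-coordinate end of the gene in IPF replicate 3, on chromosome 5 from 892703 to 892918. Both basal libraries also had a peak there, from 892089 to 893283 and from 892491 to 893426. The other 5 AT2 libraries had none within 1 kb of either end. Of 18978 autosomal protein-coding genes, 9088 had an end peak in IPF replicate 3 and 6265 in normal replicate 1. In IPF replicates 1 and 2 and normal replicates 2 and 3 the numbers were 1058, 457, 212 and 13. A peak at TRIP13 in IPF replicate 3 alone therefore cannot be told apart from the length of its list.

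**Figure D4:**
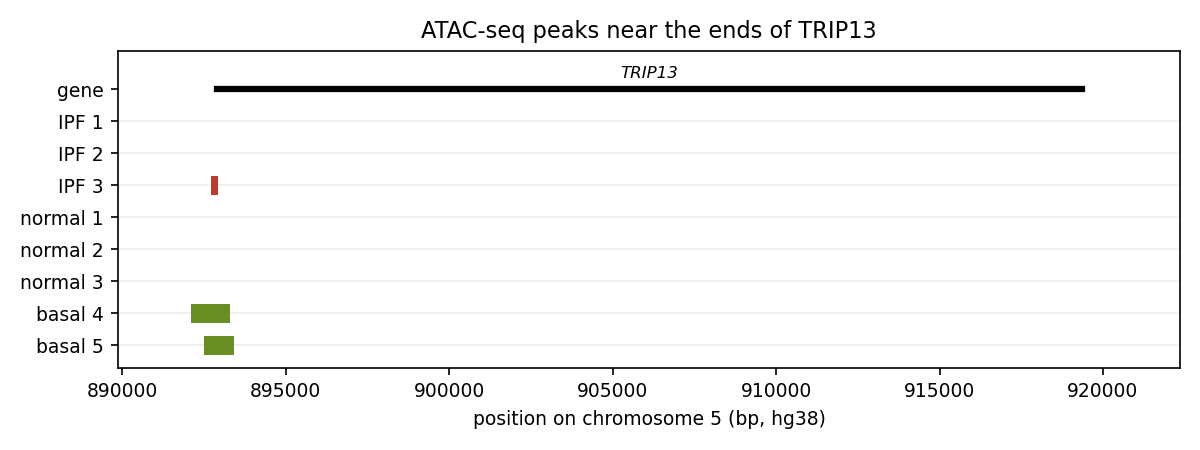
Peaks within 1 kb of either end of TRIP13 on chromosome 5 (hg38), to scale, with 1 line per ATAC-seq library under the gene. IPF replicate 3 and both basal libraries carry a peak that covers the gene end at 892884.

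AT2 identity genes carried end peaks about as often as other genes. Of 25 genes, 13 had a peak within 1 kb of an end in any AT2 library (52.0%, Wilson 95% interval 33.5 to 70.0), close to the 51.0% of all protein-coding genes. IPF replicate 3 contributed 10 and normal replicate 1 contributed 7, with 0 in the other 4. Without IPF replicate 3 the share was 28%. SFTPC had a peak in IPF replicate 3 and LAMP3 and HHIP in normal replicate 1, while CLDN18 and SFTPB had none in any library. Of 25 lipid synthesis genes, 23 had such a peak in IPF replicate 3 and 14 in normal replicate 1. Of 27 basaloid genes, the numbers were 19 and 9, and of 18 basal genes 5 and 2.

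The third comparison set AT2 against basal cells. Basal libraries held 124117 and 121467 autosomal peaks that covered 91.8 and 84.0 Mb. The log10 number of peaks was 3.31 ± 0.613 in AT2 (SD, n = 6) and 5.09 ± 0.007 in basal libraries (SD, n = 2), a difference of −1.78 (two-sided exact permutation p = 0.036, the smallest possible). The basal lists were deposited in another format, and whether calling settings matched is not given. With only 1 of the basal libraries no exact p under 0.143 was possible. The Jaccard index was 0.291 within and 0.0150 between types, but the short AT2 lists keep it low between types whatever the overlap, so it does not show which libraries share more. With the 564 top-scoring peaks of each list the difference was 0.3843 (one-sided exact permutation p = 0.036), but 79.3% and 77.4% of basal peaks had the highest score, so theirs were picked by width and this is left open. Most AT2 peaks of the longer lists lay in basal peaks. The share was 70.0%, 53.2% and 95.3% in IPF and 88.5%, 46.9% and 16.3% in normal libraries, or 72.8 ± 21.2% against 50.6 ± 36.2% (SD, n = 3 each; exact permutation p = 0.4).

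Both basal libraries and 0 AT2 libraries shared 85824 regions, among them regions in IFFO2 (chromosome 1, 18948333 to 18952588), in the adhesion gene ICAM5 (chromosome 19, 10288620 to 10293271) and in the retinoid enzyme gene DHRS3 (chromosome 1, 12617520 to 12620783). At least 2 AT2 and 0 basal libraries shared 530 regions, of which 182 were in all 6 AT2 libraries. Regions in all 6 include normal replicate 3, where 2.3% of peaks lay near gene ends and 16.3% in basal peaks. No list of artifact-prone regions was used to filter peaks here. Whether the 530 regions mark AT2 cells was not tested. Basal libraries had end peaks at 17 of 18 basal genes, KRT5 and KRT17 among them, and at 20 of 25 AT2 identity genes. Over all protein-coding genes the basal shares were 78.1% and 78.5%.

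The last comparison joined both assays. Genes with an end peak in AT2 libraries were expressed at higher levels than those without. The mean log2 CPM was 2.51 for the 5033 tested protein-coding genes with no end peak in any AT2 library. It was 4.66 for the 3557 with a peak in 1 library and 4.71 for the 4222 with a peak in 2 (SD 2.71, 2.16 and 1.90 across genes, described without a test). With a peak in 3, 4, 5 and 6 libraries it was lower again, at 4.63, 4.48, 4.1 and 4.07 over 687, 318, 99 and 7 genes. The genes with an end peak in at least 2 IPF and 0 normal libraries were 8, among them TMED1 and YIF1A. FAM230D, FAM230H, FAM230J and RNU1-3 were also in this set, and reads or peaks at these duplicated copies are uncertain. The FAM230 copies may not be independent entries in camera. The 8 genes had a median log2 fold change of 2.15 (SD 1.18, camera p = 0.0206) with 0 called by edgeR, and camera p = 0.0963 with an estimated correlation. Without normal replicate 1 the set grew to 1079 genes with a median of −0.25, which passed camera in the other direction, and without IPF replicate 2 the median was 1.35. The converse set held FGF7P3 and GPRIN2, too few to test, with a median of −0.80.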

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

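The tests of this part were chosen after the results were seen. Peaks on unplaced or unlocalized scaffolds, which no comparison above used, numbered 282.7 on average in IPF AT2 libraries (SD 36.6, n = 3) and 233.0 in normal AT2 libraries (SD 36.3, n = 3). This difference of 49.7 did not pass a two-sided exact permutation test (p = 0.2, where 0.1 is the smallest possible). The AT2 mean over 6 libraries was 257.8 against 77.0 for the 2 basal libraries (exact permutation p = 0.036, the smallest possible). Scaffold peaks made up 15.06%, 20.57% and 2.41% of the IPF lists, 2.35%, 23.86% and 30.02% of the normal lists, and 0.05% and 0.07% of the basal lists. A single peak over the whole mitochondrial genome of 16569 bp stood in every list.

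The number of AT2 peaks ranged from 564 to 12892 with both groups spread over that range. Disease state is shared within a group, so it cannot by itself give the log10 range of 1.29 within the normal group. That range exceeded the difference of 0.24 between the group means. Whether disease state adds to the peak numbers was not decided. In each of the 4 shorter lists at least 97.6% of peaks overlapped a peak of the 2 longest other AT2 lists, as a lower sensitivity would give. Artifact-prone regions called in every library would give the same, so containment cannot tell these apart. Peaks near gene ends were 55.6% and 39.5% in IPF replicates 1 and 2 and 29.1% and 2.3% in normal replicates 2 and 3. In the longest lists, IPF replicate 3 and normal replicate 1, they were 67.8% and 55.5%. Fewer reads or a higher background in the libraries with short lists stay open, and depth was not known. Of the 10 splits of the 6 libraries, 8 gave at least the 51 regions of the real split that were found in 2 or more libraries of one side and 0 of the other, with up to 6132 in another split, so the real split does not stand out. The splits with the most regions set IPF replicate 3 and normal replicate 1, the longest lists, on one side, as their length alone would give.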

How the results depend on the processing

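Thinning, extra list scalings, the block for peaks and the peak share without single libraries were added after seeing the data. Of the 97 genes named for their expression, RN7SL1 alone changed direction under an alternative, at −0.254 without IPF replicate 1, and it and RN7SK passed without IPF replicate 2 (1.98 and 3.24). Of all 162 that the rule or the text picked 8 did with library size only, 7 without IPF replicate 1 and at most 5 elsewhere. Of the 78 called ones in the text 43 passed in each of the 4 edgeR fits that left out a library other than IPF replicate 1. The number of called genes was 3429 with DESeq2, 239 against a 2-fold threshold, 916 with the replicate number as a block (814 shared with the fit without it) and 0 to 963 without one library. IPF and normal libraries come from different people, so replicate numbers are only names (correlations of same-numbered deviations −0.236 and −0.108). Of the 11 called lists an estimated correlation lost all 11, fry lost 4 and gained the Wnt list, and fits without one library lost 0 to 2 and gained 0 to 3. With the block, AT1 (−0.52, adjusted p = 0.0371) and interferon genes (adjusted p = 0.024) passed and NRF2 turned to 0.011, none of them called before. AT1 also passed with library size only and interferon genes after thinning. The direction of camera also turned in uncalled lists, with library size only (medians of inflammatory genes 0.48 and telomere genes 0.30) and without single libraries, where medians ran from −0.48 to 0.95 for granulocyte, −0.93 to 0.98 for endothelial, −0.33 to 0.78 for inflammatory, −0.55 to −0.011 for NRF2, −0.12 to 0.67 for oxidative phosphorylation, −0.38 to 0.60 for EMT and 0.007 to 0.59 for histone genes. Without a turn they ran from −0.556 to −0.265 for hypoxia, −0.40 to −0.123 for unfolded protein, −0.251 to −0.085 for telomere, −0.287 to −0.088 for chromatin, −0.686 to −0.011 for dissociation genes and −0.415 to −0.203 for TRIP13 partners. The cause was not tested.

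Leaving out single libraries gave a log10 difference in IPF and normal peak numbers of −0.103 to 0.66, and of −1.94 to −1.67 against basal lists, where 1 basal library allows no exact p under 0.143. The AT2 and basal Jaccard difference, which list lengths bound, then ran from 0.247 to 0.351, and that of IPF and normal from −0.0898 to −0.0235. Regions of 2 or more IPF and 0 normal libraries ran from 12 to 994 and the converse from 2 to 83. The former numbered 62 without extreme signal, and the latter 22 there, 7 in the better-scoring 50% of peaks and 50 with equal numbers of peaks. Regions of basal cells alone fell to 41796 in the better-scoring 50% and 256 with equal numbers, by construction. AT2 identity genes with an end peak were 28% in the better-scoring 50% and 28% to 52% without one library. The median of genes with IPF end peaks was 0.084 for at least 1 library against 0, 2.15 with an estimated correlation (not past the threshold), and −0.25 to 2.46 without one library. The normal set was at −0.24 and passed camera for at least 1 library against 0. The cause was not tested. With the replicate number as a block, the difference in IPF and normal peak numbers had an exact p of 0.75, where 0.25 is the smallest possible.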

Other observations

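The tests of explanations in this part were all chosen after the results were seen, while its gene lists were planned. Some signalling lists held called genes in both directions. Of 20 Wnt pathway genes, 5 were higher and 3 lower in IPF, and 8 were higher and 5 lower adjusted over the list alone. The Wnt transcription factor gene TCF7 rose by 2.26 on the log2 scale and DKK3, of a family of secreted Wnt inhibitors, by 1.34, while the receptor gene FZD5 (−1.95) and ZNRF3, a ligase that removes Wnt receptors (−2.06), fell. The list had a median of 0.58 and did not pass camera (adjusted p = 0.134), though it did with fry (adjusted p = 0.0387). The median was 0.356 without IPF replicate 1 and 1.001 without normal replicate 1. Of 19 interferon response genes 3 were higher, IFI6 (1.38), MX2 (2.68) and OAS1 (1.93), and 4 adjusted over the list alone, with a median of 0.66 (camera adjusted p = 0.0823). That list passed without IPF replicate 1 (median 0.61, adjusted p = 0.0156) and without normal replicate 3 (median 0.56, adjusted p = 0.038), while the median fell to 0.232 without normal replicate 1 (adjusted p = 0.289) and 0.303 without IPF replicate 2 (adjusted p = 0.538). Of 17 hypoxia and glycolysis genes, ADM (2.05) and the glucose transporter gene SLC2A1 (2.23) rose and the hexokinase gene HK2 fell by 2.08, the same number adjusted over the list alone. The median was −0.20, the mean 0.02 and camera adjusted p = 0.652.

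Of 19 unfolded protein response genes, MANF rose by 1.16 and EDEM1 fell by 1.53, with 1 higher and 2 lower adjusted over the list alone (median −0.18, camera adjusted p = 0.575). Of 19 inflammatory genes the chemokine gene CXCL5 rose by 2.27, with 1 adjusted over the list alone (median 0.11, camera adjusted p = 0.745). Of 13 EMT genes SNAI2 was called higher, at 2.98 ± 0.454 CPM in IPF (SD, n = 2) and 0.0751 ± 0.0651 CPM in normal cells (SD, n = 3), while the epithelial splicing factor gene ESRP1 was at −1.10 (edgeR adjusted p = 0.0524). Adjusted over the list alone, 1 EMT gene was higher and 1 lower (median 0.47, camera adjusted p = 0.473). In the lists of 15 NRF2 genes (median −0.34, camera adjusted p = 0.745), 27 nuclear genes of oxidative phosphorylation (0.36, adjusted p = 0.652), 11 telomere genes (−0.07, adjusted p = 0.745) and 28 chromatin regulators (−0.17, adjusted p = 0.521), edgeR called 0, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 2, 3, 2 and 6 genes, and DESeq2 called 1, 0, 1 and 3 and limma-voom 0, 0, 0 and 1. Oxidative phosphorylation passed without IPF replicate 2 (median 0.67, adjusted p = 0.0323), while the median was −0.116 without IPF replicate 1. Lists of sample quality likewise had 0 edgeR calls: 18 dissociation genes (median −0.44, camera adjusted p = 0.480) and 15 histone and other genes without long polyA tails (0.25, adjusted p = 0.652), with 0 and 3 genes at an unadjusted p under 0.05, 0 and 1 called by DESeq2 and 0 in both by limma-voom. Some RNAs of the latter list, named by the rule and compared by library after their values were seen, were highest in IPF replicate 1. RN7SL1 was at 597 CPM there and at 108 to 188 CPM in the other libraries, RN7SK at 57 against 3.73 to 8.79 and RMRP at 3.85 against 0.496 to 1.37 CPM. Without IPF replicate 1 the log2 fold change of RN7SL1 was −0.254, from 1.32. The cause was not tested, and a difference in library preparation stays open. The 4 tested MHC class II genes had no call with these tools and 0 had an unadjusted p under 0.05, and mitochondrially encoded genes were not analysed here.

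In IPF, 17 of 23 AT2 genes were lower, and 15 of 18 basal and 10 of 18 macrophage genes higher, with no list past camera at an estimated correlation. The AT2 median was −2.22 after all libraries were thinned to one total. Thinning keeps the share of each gene on average, so this cannot decide on a difference in depth. If a lower share of AT2 cells raised all other cell types alike, their lists would have similar medians. The basal and AT1 medians lay 4.34 apart, more than their SDs of 1.80 and 1.34. The basal list is part of the pattern, so this spread cannot decide. Macrophage (2.29), mesenchymal (1.61), ciliated (1.48), airway secretory (1.47) and lymphocyte (1.00) medians were also positive. Those of AT1 (−0.44), endothelial (−0.29) and erythroid genes (−2.11) were negative. A change in the mix of cells stays open. Airway basal cells carried through the isolation may be a source, since EpCAM selection would not remove them and 15 of 18 basal genes were higher, with KRT17 at 1787 and KRT5 at 838 CPM in IPF. Normal AT2 libraries also held 9 of the 18 at 5 CPM or more, and 2 are in the basaloid list. These genes are part of the pattern, so this source cannot be told apart from AT2 cells that take up basal genes. Of 10 splits of the 5 libraries, 1 gave 1484 genes and the highest of the others 0, too few splits for a share under 0.05.

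TRIP13 may follow the number of dividing cells. Its log2 fold change was 2.04 after thinning, which keeps the share of each gene on average and so cannot decide on a difference in depth. The other 29 cell cycle genes had a median log2 fold change of 0.94 between IPF and normal libraries, in the direction of TRIP13. Yet the IPF library with more TRIP13 had less of these 29 genes, with 7 of them higher there. Their median log2 CPM difference was −0.66, within their SD of 0.734, where TRIP13 differed by 1.17. With 1 library on each side this decides nothing, and disease state stays open and untested.

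Called genes differed in how often they carried an end peak in the pair of longest AT2 lists. Of 600 genes higher in IPF, 31.3% (Wilson 95% interval 27.8 to 35.2) had one in IPF replicate 3 and 13.2% (10.7 to 16.1) in normal replicate 1. Of 662 lower genes the shares were 52.6% (48.8 to 56.4) and 48.2% (44.4 to 52.0), and of 12661 genes without a call 61.9% (61.0 to 62.7) and 43.0% (42.2 to 43.9). In the basal libraries the higher genes had 88.7% and 89.7%, and the genes without a call 90.6% in both. Each share is of 1 library and has no replicate check. The shares were not matched for expression level, which went with end peaks. Genes with no AT2 end peak had a mean log2 CPM of 2.51 and a median log2 fold change of 0.41. Those with a peak in 1 AT2 library had 4.66 and 0.005. Whether expression level explains the shares was not tested.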
